A study of Mus musculus with 21 samples.

How the data were processed

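RNA sequencing of cultured mouse NK cells from 4 groups was analysed: Cre only (4 libraries), Ikzf1 KO (4), Ikzf3 KO (4) and DKO (3). The labels describe 21 samples in 6 groups, called biological replicates; the 6 directly sorted samples have no column in the deposited table and were not analysed here. Per the labels, NK cells were sorted from spleen and cultured with IL-15 at 50 ng/ml. RNA was extracted with RNeasy kits, RNA integrity numbers were above 7.0, and stranded libraries of polyadenylated RNA were made with NEBNext Ultra II Directional kits. Single-end reads of 75 bp were taken on a NextSeq 500, with about 20 megareads intended per sample. The submitters' processing notes name STAR, featureCounts, limma 3.34.9 and the genome build mm10, without settings.

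The deposited file is 1 table of RPKM (reads scaled to gene length in kilobases and to library size) for 11736 genes, as the authors computed it, with no counts. The values were checked against exon lengths of GENCODE mouse release 21, in which 11732 of the genes were found and 4 were not. In each column the smallest steps between values times length gave the value of a single read, and so the depth: 11291 genes (96.2%) came out as whole reads in all libraries within 0.02 read. Depths recovered in this way ran from 8.6 to 21.2 megareads in these 11291 genes, which leaves out the reads of the other genes. Summed over all genes found, RPKM times length in kilobases ranged from 921953 to 1129253, so the divisor was not the plain total of their reads. Depth therefore limits only the weakly expressed genes. Between libraries of the same group, counts differed by more than sampling noise, with a chi-square per degree of freedom of 3.42 to 230.79, so the spread between replicates sets the precision. The column names do not state the culture. Ikzf3 KO and DKO samples exist only as cultured cells, and 4 columns each of Ikzf1 KO and Cre only match only the cultured groups, since the directly sorted ones have 3 each.

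The analysis was planned before the data were examined, apart from what is marked as added. Genes with an RPKM of at least 1 in at least 3 of the 15 libraries were kept (10032 genes). Values were transformed to log2(RPKM + 0.5) and fitted in limma 3.58.1 (R 4.3.3) with 1 mean per group for all 15 libraries together, a mean-variance trend and robust empirical Bayes moderation, on 11 residual degrees of freedom. The 5 contrasts and the departure of the DKO cells from the sum of the single deletions were tested, 2-sided. A gene was called changed at a Benjamini-Hochberg adjusted p below 0.05 over all genes of a contrast. Values in the text are mean RPKM ± SD and log2 fold change ± SE. Figures and recovered depths were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

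A set of 33 gene lists (NK functions, signalling, metabolism and markers of other cell types the gate could hold) was fixed before the data were examined. For each list and contrast the members called were counted, over all genes and adjusted over the list alone. Lists with at least 3 measured members were tested with camera at a preset correlation of 0.01 between genes, repeated with the correlation estimated per list, and with fry, which tests whether a list's genes move without comparing them with other genes. Camera compares a list with the other genes, and its p values were adjusted over the lists of a contrast.

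Named genes followed a rule written at the same time. It took Ikzf1 and Ikzf3, and in each comparison the 8 largest rises and 8 largest falls among genes called changed. These genes had a mean RPKM of at least 5 in the higher group and no overlap between the libraries of the groups, and predicted genes and antigen receptor segments were left out. For the test of additivity it took 5 genes per direction, without the condition on overlap. It also took up to 4 members per list and comparison with the smallest adjusted p. The text shows those of most interest, preferring genes called under every alternative, a choice made after the values were seen. Some genes chosen by this rule are not reported here, and they stayed in the list counts and tests.

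The main test was checked on simulated data, with the depths and the spread per gene of the real libraries and 100 genes, of a mean RPKM of at least 5, given each of a 2-fold and a 4-fold change. At 2-fold it recovered 77% in Ikzf1 KO against Cre only (9590 genes run) and 66% in Ikzf3 KO against Cre only (9598 genes run). It recovered 56% in DKO against Cre only (9596 genes run), 64% in DKO against Ikzf1 KO (9587 genes) and 69% in DKO against Ikzf3 KO (9606 genes). At 4-fold it recovered 97%, 99%, 91%, 99% and 95% in the same order. Among unchanged genes it called 5, 10, 9, 6 and 7. The simulated libraries started from Cre only means and had independent noise, with a single spread per gene for all groups. Sampling noise of reads was added to this spread, which already holds it, so that noise entered more than once. The simulated libraries held neither the unequal spread between the real groups nor the libraries that stand apart within groups. These rates therefore do not cover errors from that structure.

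The alternatives fixed in advance were pseudocounts of 0.1 and 1, no filter, a filter of RPKM 5, rescaling by median ratios, quantile normalization, array weights, moderation without the robust option, fits of only the 2 groups compared and leaving out each library in turn. Added after seeing the data were voom on the recovered reads and fits without S3 and S4, without S16 and S17 and without S18 and S19. Added too were fits without Ikzf3 KO libraries, with a term for the set of S5, S15, S18 and S19 or with only libraries outside it. Shared changes were also counted with the controls split into pairs. Each count of changed genes was compared with those from other splits of the same libraries.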

Results

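Messenger RNA of mouse natural killer (NK) cells was sequenced to compare cells lacking Ikaros (gene Ikzf1), Aiolos (gene Ikzf3) or both with cells that carried only the Cre recombinase. Both proteins are zinc finger transcription factors of lymphocytes. NK cells were sorted from spleen and cultured in interleukin 15 (IL-15), a cytokine on which NK cells depend. The deposited table held 4 Cre only libraries (columns S16 to S19), 4 libraries of the Ikzf1 knockout (KO; S12 to S15), 4 libraries of the Ikzf3 KO (S1 to S4) and 3 libraries of the double knockout (DKO; S5 to S7). The labels speak of biological replicates and state at least 3 per genotype. The column names give the genotype but not the culture, and they were assigned to the cultured groups because only these have matching group sizes. The 6 directly sorted samples of the labels were not analysed here. Reads were recovered from the steps between the values of each column. In the 11291 genes that came out as whole reads in all libraries they ranged from 8.6 to 21.2 megareads per library. They came to 14.368, 14.951, 13.225 and 15.966 megareads in the Cre only libraries S16 to S19 and 16.7, 11.261, 14.019 and 21.25 megareads in the Ikzf1 KO libraries S12 to S15. The Ikzf3 KO libraries S1 to S4 had 11.129, 8.613, 12.56 and 12.736 megareads. Depths of 12.805, 18.585 and 13.907 megareads were found in the DKO libraries S5 to S7.

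The deleted genes themselves were lower in the cells that should lack them, without reaching 0. Ikzf1 (ENSMUSG00000018654, chromosome 11, positions 11685003 to 11772926 of mm10, plus strand) stood at 61.9 ± 5.22 (SD, n = 4) RPKM (reads scaled to gene length and library size) in Cre only cells. It stood at 19.1 ± 0.662 (SD, n = 4) in Ikzf1 KO cells, 30.3 ± 7.12 (SD, n = 3) in DKO cells and 81.4 ± 6.34 (SD, n = 4) in Ikzf3 KO cells. Ikzf3 (ENSMUSG00000018168, chromosome 11, positions 98464902 to 98546031, minus strand) stood at 41.8 ± 3.68 (SD, n = 4) RPKM in Cre only cells and 48.3 ± 1.52 (SD, n = 4) in Ikzf1 KO cells. It stood at 17.8 ± 2.37 (SD, n = 4) in Ikzf3 KO cells and 21.5 ± 1.96 (SD, n = 3) in DKO cells. Against Cre only cells, Ikzf1 fell in Ikzf1 KO cells by a log2 fold change of -1.67 ± 0.13 (SE; adjusted p = 3.26e-06 by limma with Benjamini-Hochberg adjustment) and in DKO cells by -1.04 ± 0.14 (adjusted p = 0.000116). Ikzf3 fell in Ikzf3 KO cells by -1.21 ± 0.11 (adjusted p = 3.94e-05) and in DKO cells by -0.94 ± 0.12 (adjusted p = 0.000102). Ikzf1 had a log2 change of 0.39 ± 0.13 in Ikzf3 KO cells (adjusted p = 0.0531, past the threshold after rescaling by median ratios and with array weights). Ikzf3 had one of 0.21 ± 0.11 in Ikzf1 KO cells (adjusted p = 0.335). The values cover the whole gene, so reads of exons that were not deleted count in them. All fold changes here are taken on log2(RPKM + 0.5), which understates the changes of genes with low values.

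**Figure D1:**
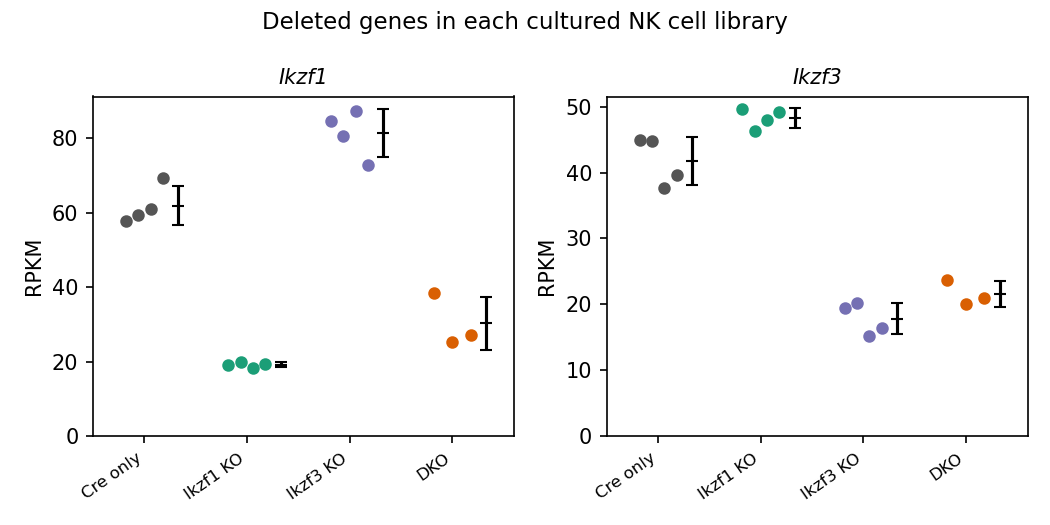
RPKM of Ikzf1 and Ikzf3 in each of the 15 cultured libraries by genotype, with the mean and SD of each group. Ikzf1 had a mean of 61.9 in Cre only and 19.1 in Ikzf1 KO libraries, and Ikzf3 a mean of 41.8 in Cre only and 17.8 in Ikzf3 KO libraries.

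On the first principal components of all genes kept, DKO and Ikzf1 KO libraries stood apart from Cre only libraries, but the Ikzf3 KO libraries did not form a group of their own. The first component held 37.6% of the variance and the second 24.3%. S1 and S2 lay at -6.49 and -7.62 on the first, where Cre only libraries ran from -6.63 to 6.29, while S3 and S4 lay at -70.8 and -68.2. S1 and S2 were parted from Cre only libraries on the third component, both at -29.7 against -1.53 to 19.6. The Ikzf3 KO group was the most spread, with a median SD of 0.363 per gene on the log2 scale, against 0.174 in Cre only, 0.123 in Ikzf1 KO and 0.21 in DKO libraries. Across genes, which are not independent replicates, S3 and S4 correlated at 0.974 and S1 and S2 at 0.99, but S1 and S2 correlated with S3 and S4 at only 0.895 to 0.913, less than with Cre only libraries (0.954 to 0.965). In the Cre only group S16 and S17 correlated at 0.993 and S18 and S19 at 0.988, against 0.964 to 0.975 across these pairs. The parting of S18 and S19 from S16 and S17 ran across genotypes. Each of the 72 groupings of 1 DKO, 1 Ikzf1 KO and 2 Cre only libraries was tried as a term beside genotype. The set of S5, S15, S18 and S19 gave 875 genes and the next grouping 33. The phosphatase gene Dusp2 was higher in this set by a log2 change of 1.46 ± 0.11 (adjusted p = 0.000336) and the chemokine gene Ccl1 lower by -2.71 ± 0.24 (adjusted p = 0.00106), both named after their values were seen. On these genes, with S16 and S17 at 0 and S18 and S19 at 1, the Ikzf3 KO libraries S1 and S2 lay at 0.09 and 0.07 and S3 and S4 at 0.37 and 0.39. None was clearly in the set, so only comparisons without Ikzf3 KO were fitted with it as a term. No label gives a day, animal or batch that parts these libraries. The counts are therefore also given without S3 and S4, without S16 and S17 and without S18 and S19, and where possible with the set as a term or with only libraries outside it, choices made after the data were seen.

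**Figure D2:**
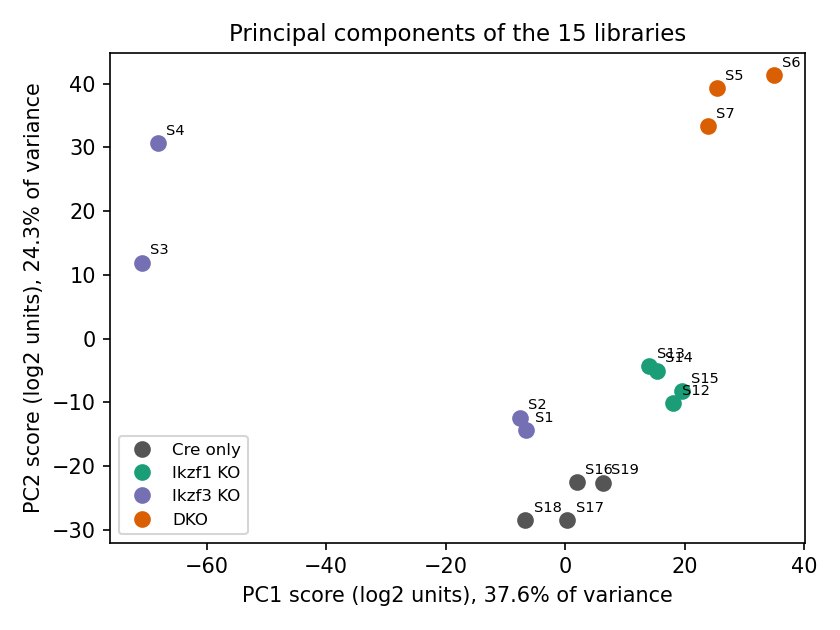
The 15 libraries on the first 2 principal components of log2(RPKM + 0.5), in units of the component scores, coloured by genotype. The axes hold 37.6% and 24.3% of the variance, and S3 and S4 lie apart from S1 and S2.

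Of 10032 genes tested, 634 changed in Ikzf1 KO cells against Cre only cells (355 higher, 279 lower), 1423 in Ikzf3 KO cells (632 higher, 791 lower) and 1872 in DKO cells (809 higher, 1063 lower). DKO cells differed from Ikzf1 KO cells in 750 genes (377 higher, 373 lower) and from Ikzf3 KO cells in 2012 genes (1024 higher, 988 lower). The main fit shared a single spread over all groups, and the order of the Ikzf1 KO and Ikzf3 KO counts depended on it. With only the 2 groups compared in the fit, 1927 genes changed in Ikzf1 KO and 431 in Ikzf3 KO against Cre only cells. With array weights these counts were 3634 and 2367. DKO against Ikzf3 KO gave 664 genes with only its 2 groups in the fit. Single libraries also decided much of these sizes. The Ikzf3 KO count was 2985 without S1, 2383 without S2, 889 without S3, 819 without S4, 858 without S16, 832 without S17 and 845 without S18. The Ikzf1 KO count was 338 without S12, 340 without S13, 332 without S14 and 357 without S18. The DKO count was 976 without S6. DKO against Ikzf1 KO gave 335 genes without S6, 490 without S7, 422 without S12, 493 without S13 and 454 without S14. DKO against Ikzf3 KO gave 3080 genes without S1 and 1169 without S6.

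**Figure D3:**
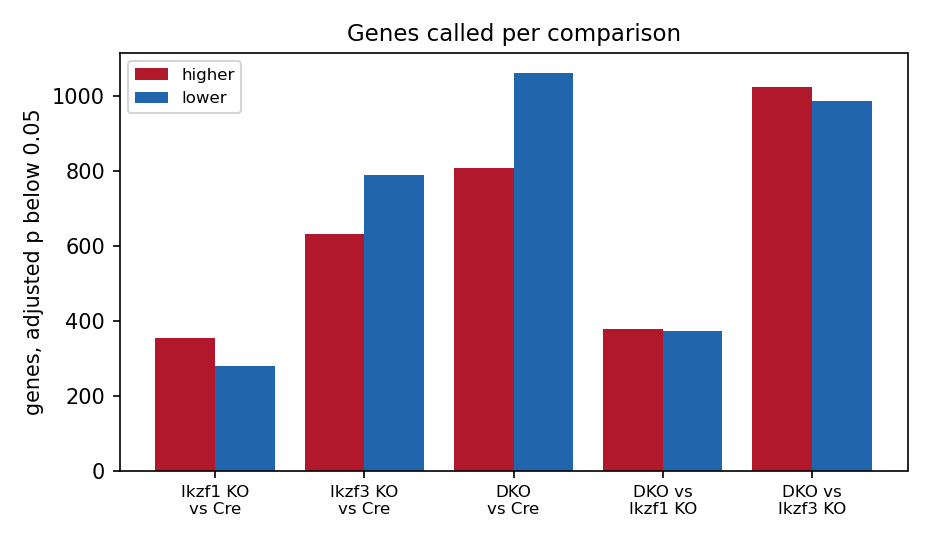
Number of genes higher and lower at an adjusted p below 0.05 in each of the 5 comparisons of cultured NK cells. The bars start at 0, and the largest count of higher genes is 1024 in DKO against Ikzf3 KO cells.

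The comparison of Ikzf1 KO with Cre only cells asks which transcripts depend on Ikaros while Aiolos is intact. Among the largest rises was that of B4galnt2, a glycosyltransferase gene, from 0.66 ± 0.336 (SD, n = 4) to 15.9 ± 3.33 (SD, n = 4) RPKM. Ifitm3, an antiviral membrane protein gene, rose from 54.9 ± 34.6 (SD, n = 4) to 461 ± 69 (SD, n = 4) RPKM. Nrp1, a semaphorin co-receptor gene, rose by a log2 change of 3.09 ± 0.25, and the serine protease genes Ctsg and Cma1, known from neutrophil and mast cell granules, rose by 3.67 ± 0.53 and 3.64 ± 0.64. Jaml, encoding a junctional adhesion protein, fell from 19.2 ± 2.83 (SD, n = 4) to 2.33 ± 0.786 (SD, n = 4) RPKM (log2 change -2.83 ± 0.23; limma with Benjamini-Hochberg, adjusted p = 5.39e-06). The cadherin gene Cdh17 and the calcium-binding S100a4 fell as well, with log2 changes of -2.23 ± 0.36 and -2.24 ± 0.31. Cd27, a receptor of less mature NK cells, had a log2 change of -2.04 ± 0.20 and Itgam, the CD11b chain of mature NK cells, one of -1.61 ± 0.26, but the lists of immature and mature NK genes were not called. Of 19 immature NK genes 2 fell, none rose and 17 did not pass, as when adjusted over the list alone, where 2 fell (camera adjusted p = 0.161). Of 17 mature NK genes 3 rose, Cma1 among them, 2 fell and 12 did not pass; adjusted over the list alone 4 rose and 3 fell (camera adjusted p = 0.944).

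By list, the cell cycle genes formed the largest group in Ikzf1 KO cells. Of 38 measured, 9 rose, among them Cdc20 and Bub1b of the mitotic checkpoint (log2 changes 1.08 ± 0.21 and 0.99 ± 0.21), none fell and 29 did not pass; 28 rose when adjusted over the list alone. The list was called higher by camera (adjusted p = 4.63e-15, median log2 change 0.79), a call lost at adjusted p = 0.647 with an estimated correlation and at 0.0622 with fry. This group moved with the Cre only pairs: without S16 and S17 no member was called and the median was 0.42, and without S18 and S19 the number called was 23 and the median 1.13. With the set as a term 27 were called and the median was 0.84. Of 23 homing and adhesion genes 5 fell, among them Itgam and the CD69 gene, the latter by -1.20 ± 0.26, and 18 did not pass. The counts adjusted over the list alone were 1 rise and 9 falls (camera adjusted p = 0.00053, and adjusted p = 0.0678 with an estimated correlation). Of 21 interferon-stimulated genes 3 rose, led by Oasl2 at 2.76 ± 0.37, and 18 did not pass; adjusted over the list alone 5 rose and 1 fell (camera adjusted p = 0.017; adjusted p = 0.647 with an estimated correlation, 0.0922 without S16 and S17, 0.0851 with the set as a term and 0.175 with fry). Of 26 cytotoxic effector genes Prf1 and Ctsd fell and 24 did not pass (adjusted over the list alone 5 rose and 7 fell; camera adjusted p = 0.465; median -0.09 but mean 0.23). Prf1, encoding the pore-forming perforin, went from 720 ± 291 (SD, n = 4) to 145 ± 4.05 (SD, n = 4) RPKM, with a log2 change of -2.21 ± 0.53 (limma with Benjamini-Hochberg, adjusted p = 0.022).

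The fall of Prf1 in Ikzf1 KO cells lost its call when S12, S13, S14, S16, S17 or S18 was left out, with log2 changes between -2.47 and -1.98 and an adjusted p of up to 0.072, and without S16 and S17 together (-1.79, adjusted p = 0.205). Ctsd, at -0.63 ± 0.17, lost its call without any of S12 to S15 or S17 to S19, with log2 changes between -0.73 and -0.53 over all single libraries left out and an adjusted p of up to 0.143. It also lost the call without S18 and S19 (-0.44, adjusted p = 0.305) and after quantile normalization (-0.53, adjusted p = 0.135). The calls of Cdc20, Bub1b and Cd69 were lost without S16 and S17. In total 366 genes were called without S16 and S17, of which 288 were also called with all libraries, and 588 without S18 and S19, of which 365 were. Without S3 and S4, which belong to neither group but enter the shared variance, 1698 genes were called. With the set as a term and Ikzf3 KO libraries left out, 1982 genes were called, among them 630 of the 634, and with only libraries outside the set 2993, among them 583.

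The comparison of Ikzf3 KO with Cre only cells asks which transcripts depend on Aiolos while Ikaros is intact. The chemokine gene Ccl5 fell from 689 ± 90.1 (SD, n = 4) to 33.2 ± 14.8 (SD, n = 4) RPKM, a log2 change of -4.45 ± 0.32 (limma with Benjamini-Hochberg, adjusted p = 3.99e-06). The Schlafen family gene Slfn8 fell from 18.4 ± 1.11 (SD, n = 4) to 0.74 ± 0.354 (SD, n = 4) RPKM. The chemerin receptor gene Cmklr1 and the Notch ligand gene Dll1 fell by -3.03 ± 0.41 and -2.84 ± 0.35. Granzyme genes of the Gzmd cluster rose, with log2 changes of 4.02 ± 0.81 for Gzmd and 5.32 ± 1.03 for Gzmg. The former went from 444 ± 381 (SD, n = 4) to 5140 ± 2260 (SD, n = 4) RPKM and the latter from 90.8 ± 81.8 (SD, n = 4) to 2570 ± 1200 (SD, n = 4) RPKM. These paralogs are near identical in sequence, so reads may be divided between them arbitrarily. Ctsg, encoding cathepsin G, rose by 5.64 ± 0.53 and Gng11, a G protein subunit gene, by 3.51 ± 0.41.

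By list, 7 of 16 cytokine and chemokine genes fell in Ikzf3 KO cells and 9 did not pass, with 7 falls when adjusted over the list alone. Beside Ccl5, the macrophage inflammatory protein genes Ccl3 and Ccl4 fell by -3.33 ± 0.82 and -3.10 ± 0.80. Ccl3 lost its call without S3, S16 or S17 (log2 changes -3.98 to -2.51, adjusted p up to 0.0543) and Ccl4 without S3, S4, S16 or S17 (-3.72 to -2.36, adjusted p up to 0.0655). Camera called the list lower (adjusted p = 0.00158), with an adjusted p = 0.593 with an estimated correlation and 0.0906 without S16 and S17. Of 19 genes of IL-2 and IL-15 signalling 7 fell and 12 did not pass, among them Il2rg, encoding the shared cytokine receptor chain, from 175 ± 15.1 (SD, n = 4) to 77.6 ± 17 (SD, n = 4) RPKM. When adjusted over the list alone 1 rose and 9 fell (camera adjusted p = 0.021; adjusted p = 0.593 with an estimated correlation; 0.0972 without S16 and S17). Of 26 cytotoxic effector genes 7 rose, Rab27a and 6 granzyme genes with Gzmk at 2.00 ± 0.33 among them, and 4 fell, among them Tnfsf10, encoding the death ligand TRAIL, at -1.19 ± 0.22. The other 15 did not pass, and adjusted over the list alone 7 rose and 6 fell (camera adjusted p = 0.56). Of 14 checkpoint genes Havcr2 (TIM-3) and Ctla4 rose, the former by 2.19 ± 0.41, 5 fell, among them Entpd1 (CD39) and Tox at -1.74 ± 0.27 and -1.69 ± 0.18, and 7 did not pass. The counts adjusted over the list alone were 2 rises and 6 falls (camera adjusted p = 0.242). Among 25 further NK receptor genes 2 rose, with Klrg1 at 1.58 ± 0.26, and 6 fell, with the activating receptor gene Cd226 at -1.75 ± 0.27; 17 did not pass, and adjusted over the list alone 3 rose and 7 fell (camera adjusted p = 0.213). Of 11 Ly49 receptor genes 4 fell, with Klra5 at -1.89 ± 0.31, none rose and 7 did not pass; 4 fell when adjusted over the list alone (camera adjusted p = 0.116).

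None of the 24 genes of ribosome biogenesis and MYC targets passed in Ikzf3 KO cells, alone or over the list, yet camera called the list lower (adjusted p = 0.021, median -0.86). This rested on S3 and S4: without them the list was called higher (adjusted p = 0.0176, median 0.31), and the adjusted p was 0.758 with an estimated correlation, 0.101 without S16 and S17 and 0.278 with fry. In total 958 genes were called without S3 and S4, of which 595 were also called with all libraries. The count was 555 without S16 and S17, of which 459 were shared, and 740 without S18 and S19, of which 553 were.

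The comparison of DKO with Cre only cells asks what follows when both factors are missing. Prf1 (perforin) fell from 720 ± 291 (SD, n = 4) to 35.5 ± 28.6 (SD, n = 3) RPKM, a log2 change of -4.60 ± 0.57 (limma with Benjamini-Hochberg, adjusted p = 6.72e-05). Entpd1 fell by -4.34 ± 0.29, the leukotriene B4 receptor gene Ltb4r1 by -4.06 ± 0.21 and the integrin gene Itgax (CD11c) by -3.92 ± 0.41. Igfbp7, encoding a secreted growth factor binding protein, rose from 0.0429 ± 0.0858 (SD, n = 4) to 67.7 ± 10.2 (SD, n = 3) RPKM. This was the largest rise among the genes that met the naming rule, which leaves out antigen receptor segments. Cd3e, a chain of the CD3 complex of T cells, rose from 1.52 ± 1.5 (SD, n = 4) to 37.3 ± 10.9 (SD, n = 3) RPKM. Ikzf2 (Helios), another member of the Ikaros family, rose by 3.40 ± 0.40.

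**Figure D4:**
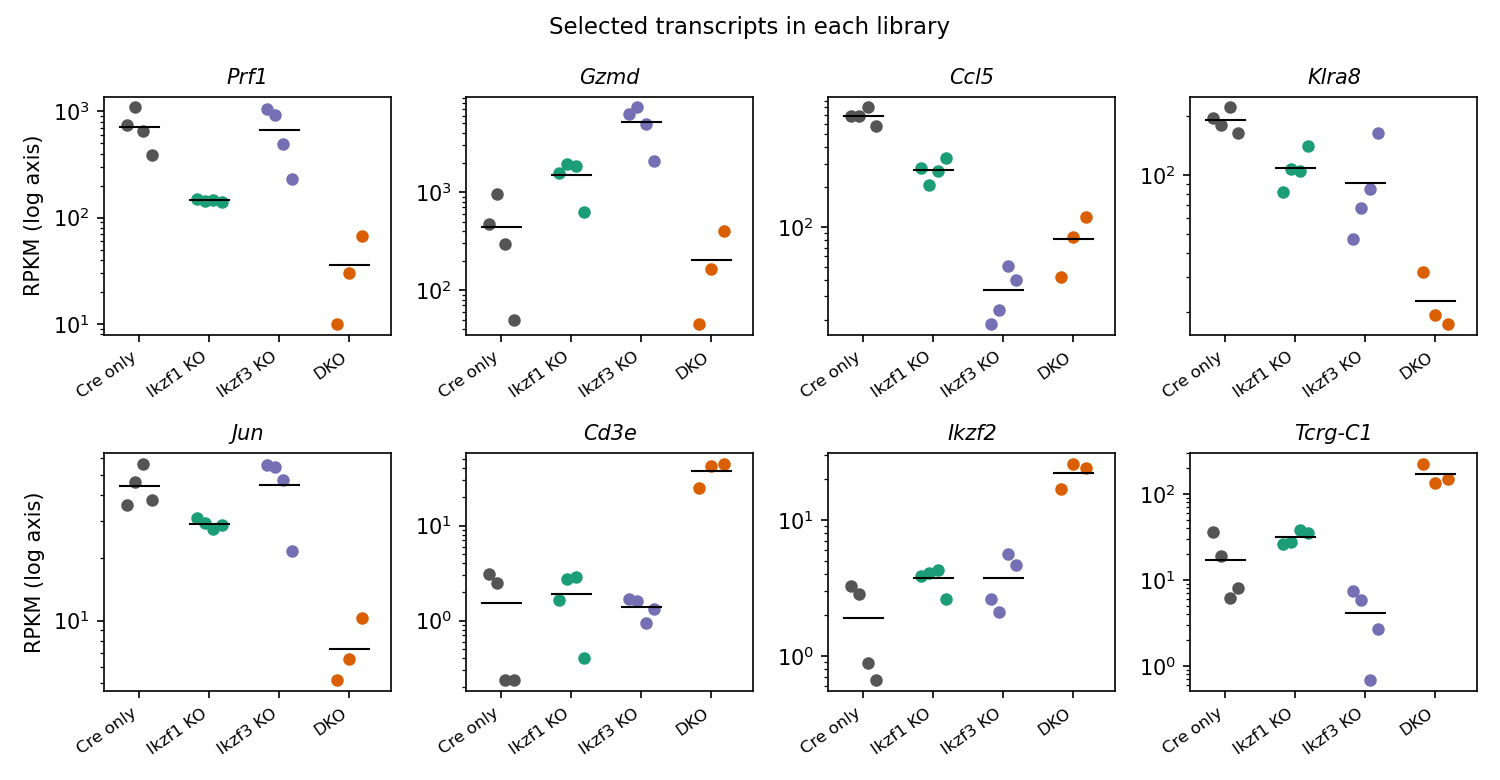
RPKM of Prf1, Gzmd, Ccl5, Klra8, Jun, Cd3e, Ikzf2 and Tcrg-C1 in each library by genotype on a log axis, with a line at each group mean and values below 0.02 drawn at 0.02. Prf1 had a mean of 720 in Cre only and 35.5 in DKO libraries, and Cd3e one of 1.52 in Cre only and 37.3 in DKO libraries.

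Camera called the cytotoxic and Ly49 lists lower in DKO cells, calls that were lost with an estimated correlation, and did not call the list of other NK receptors. Of 26 cytotoxic effector genes 9 fell, among them Gzma and Prf1 (Gzma at -1.95 ± 0.31), 4 rose, among them Gzmk and Gzmm at 1.98 ± 0.36 and 1.64 ± 0.32, and 13 did not pass. When adjusted over the list alone 4 rose and 14 fell (camera adjusted p = 0.0108; adjusted p = 0.395 with an estimated correlation; 0.0739 without S16 and S17). Of 11 Ly49 receptor genes 5 fell, with Klra8 (Ly49H) going from 190 ± 24.4 (SD, n = 4) to 22.9 ± 7.97 (SD, n = 3) RPKM, Klra1 rose and 5 did not pass. The same counts held adjusted over the list alone (camera adjusted p = 0.0203; adjusted p = 0.553 with an estimated correlation and 0.0526 with only libraries outside the set). Ly49 genes are close paralogs, and their reads may be shared. Of 25 further NK receptor genes 2 rose, 5 fell and 18 did not pass, with 2 rises and 6 falls adjusted over the list alone (median 0.03; camera adjusted p = 0.571). Of 14 checkpoint genes 6 fell, among them Lag3 and Pdcd1lg2 at -1.51 ± 0.21 and -2.13 ± 0.31, none rose and 8 did not pass. With the p adjusted over the list alone 8 fell (camera adjusted p = 0.000195; adjusted p = 0.212 with an estimated correlation). The mature NK list had 8 falls, led by Itgam at -3.53 ± 0.28, and 3 rises, among them the egress receptor gene S1pr1 at 3.58 ± 0.44, with 6 of 17 not passing. It had 3 rises and 9 falls adjusted over the list alone (camera adjusted p = 0.0492; adjusted p = 0.395 with an estimated correlation, 0.311 without S16 and S17, 0.0744 without S3 and S4, 0.0518 without S18 and S19, 0.0654 with voom, 0.0536 with the set as a term and 0.104 with only libraries outside it). The immature NK list had 10 rises, among them Gpr183 and Il7r at 3.18 ± 0.28 and 2.15 ± 0.43, and 1 fall, of Kit, with 8 of 19 not passing. These counts were the same adjusted over the list alone (camera adjusted p = 0.00128; adjusted p = 0.395 with an estimated correlation and 0.0749 with only libraries outside the set). Of the 12 AP-1 genes Jun fell from 44 ± 9.45 (SD, n = 4) to 7.32 ± 2.64 (SD, n = 3) RPKM. Another 4 members fell, Batf3 rose by 3.32 ± 0.28 and 6 did not pass, as when adjusted over the list alone (camera adjusted p = 0.15).

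Glycolysis genes fell in DKO cells: 12 of 18 fell, none rose and 6 did not pass, and 15 fell when adjusted over the list alone. Gapdh went from 567 ± 69.1 (SD, n = 4) to 209 ± 111 (SD, n = 3) RPKM, and Eno1 and Pkm, encoding enzymes of the last steps, fell by -1.56 ± 0.30 and -1.43 ± 0.25. The list had a median log2 change of -1.49 (camera adjusted p = 1.37e-06; adjusted p = 0.395 with an estimated correlation). The size moved with the libraries. Without S16 and S17 the number called was 5 and the median -1.05, and without S18 and S19 they were 15 and -1.88. Without S6 the number called was 8, without S5 9 (median -1.08) and without S7 15 (median -1.96). With the set as a term 17 fell (median -1.59). Slc16a3, a lactate transporter gene named after its values were seen, stood at 163 and 176 RPKM in S16 and S17 and at 33.6 and 32.1 in S18 and S19, against 1.17, 10.9 and 59.5 in the DKO libraries S5 to S7. T cell markers rose together: of the 20 listed 12 were measured, of which 8 rose, none fell and 4 did not pass. With the p adjusted over the list alone 8 rose (median 1.65, camera adjusted p = 0.000144, and adjusted p = 0.212 with an estimated correlation). Trac, the T cell receptor alpha constant segment, went from 18 ± 8.13 (SD, n = 4) to 128 ± 54.2 (SD, n = 3) RPKM, and all 16 measured beta chain variable segments rose. Of 6 gamma delta T cell genes 4 rose, with Tcrg-C1 going from 17.2 ± 13.5 (SD, n = 4) to 169 ± 48.9 (SD, n = 3) RPKM. Trdv4 fell by -2.55 ± 0.29, and adjusted over the list alone again 4 rose and 1 fell (camera adjusted p = 0.0566). The T cell marker Bcl11b did not pass (log2 change -0.43, adjusted p = 0.261), nor did Cd3g (0.76, adjusted p = 0.398); both were named after their values were seen. Beside them both B cell markers rose, with Ighm at 2.55 ± 0.41 and Cd79b at 1.18 ± 0.28, whose call was lost without S6 (log2 change 0.88, adjusted p = 0.0735) and without S18 and S19 (log2 change 0.96, adjusted p = 0.0899). Cd3e itself varied among Cre only libraries from 0.237 in S18 to 3.1 in S16. Of the 12 T cell markers 4 were lower in the set and none higher, and with the set as a term 8 rose in DKO cells as before (median 1.61). Without S16 and S17 the DKO count was 1083, of which 979 genes were also called with all libraries, and without S18 and S19 it was 1360, of which 1111 were. It was 3642 without S3 and S4, 3894 with the set as a term (1838 of the 1872 among them) and 4655 with only libraries outside the set (1643 among them).

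The comparison of DKO with Ikzf1 KO cells asks what the loss of Aiolos adds where Ikaros is already missing. Ikzf1 itself was higher in DKO than in Ikzf1 KO cells (log2 change 0.63 ± 0.14, adjusted p = 0.0119), with 38.4 RPKM in S5, 25.3 in S6 and 27.2 in S7 against 18.3 to 19.9, so its remaining transcripts were not equal in both groups. Ikzf3 was lower by -1.15 ± 0.12. Igfbp7 and Cd3e rose by log2 changes of 5.96 ± 0.20 and 4.09 ± 0.57, and Gpr183, a receptor guiding lymphocyte positioning, by 3.40 ± 0.28. Entpd1 fell by -3.93 ± 0.29 and the granzyme gene Gzmf from 41.2 ± 23.1 (SD, n = 4) to 0.584 ± 0.465 (SD, n = 3) RPKM. Of 12 T cell markers 8 rose, none fell and 4 did not pass, with 10 when adjusted over the list alone (camera adjusted p = 1.86e-10). This was the only list test of the series that kept its call with an estimated correlation (adjusted p = 0.0225). Of 19 immature NK genes 10 rose, among them Cd27 at 2.42 ± 0.22, Kit fell and 8 did not pass. With the p adjusted over the list alone 13 rose and 2 fell (camera adjusted p = 2.24e-07; adjusted p = 0.129 with an estimated correlation). Of 26 cytotoxic effector genes 8 fell, with Gzma at -2.32 ± 0.31, Gzmk and Gzmm rose and 16 did not pass. When adjusted over the list alone 4 rose and 12 fell (camera adjusted p = 0.0147; adjusted p = 0.322 with an estimated correlation, 0.0576 without S3 and S4, 0.0527 with the set as a term and 0.116 with only libraries outside it). Of 23 homing and adhesion genes 7 rose and 2 fell, Itgam and Itgax, and 14 did not pass; adjusted over the list alone 10 rose and 3 fell (camera adjusted p = 0.0105; adjusted p = 0.129 with an estimated correlation and 0.0659 with only libraries outside the set). Cell cycle genes gave no call among 38. Without S3 and S4, again outside both groups, 2125 genes were called. The count was 706 without S16 and S17 and 730 without S18 and S19, likewise outside both groups. It was 2671 with the set as a term (741 of the 750 among them) and 3943 with only libraries outside the set (646 among them).

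The comparison of DKO with Ikzf3 KO cells asks what the loss of Ikaros adds where Aiolos is already missing. Of the 6 granzyme genes that rose in Ikzf3 KO cells, 5 were lower in DKO cells and Gzmk did not pass (log2 change -0.01 ± 0.36, adjusted p = 0.984). Gzmd stood at 5140 ± 2260 (SD, n = 4) RPKM in Ikzf3 KO and 203 ± 179 (SD, n = 3) in DKO cells, and Gzmg fell by a log2 change of -7.10 ± 1.11. Prf1 fell by -4.37 ± 0.57 and Havcr2 (TIM-3) by -4.55 ± 0.44. Cd74, the invariant chain of antigen presentation, rose from 0.602 ± 0.129 (SD, n = 4) to 24.9 ± 8.91 (SD, n = 3) RPKM, and Cxcr3, a chemokine receptor gene, by 2.59 ± 0.26. Of 26 cytotoxic effector genes 13 fell, 3 rose, with Tnfsf10 at 2.02 ± 0.24, and 10 did not pass. When adjusted over the list alone 5 rose and 16 fell (camera adjusted p = 0.00285; adjusted p = 0.288 with an estimated correlation). Of 21 interferon-stimulated genes 10 rose, among them Bst2 at 1.33 ± 0.24, 1 fell and 10 did not pass. The counts adjusted over the list alone were 13 rises and 1 fall (camera adjusted p = 0.000865; adjusted p = 0.435 with an estimated correlation). Of 18 glycolysis genes 10 fell, with Pgk1 at -2.09 ± 0.39, and 8 did not pass; 14 fell when adjusted over the list alone (camera adjusted p = 2.76e-06; adjusted p = 0.343 with an estimated correlation). T cell markers rose in 9 of 12 cases, as when adjusted over the list alone (camera adjusted p = 0.000112; adjusted p = 0.288 with an estimated correlation). Without S3 and S4, 1958 genes were called, of which 1230 were also called with all libraries. The count was 1773 without S16 and S17 and 1843 without S18 and S19.

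The test of additivity asks whether the DKO cells differ from the sum of the log2 changes of the single deletions. It called 657 genes, 364 above the sum and 293 below it. The count was 344 without S6, 400 without S12, 379 without S13, 381 without S14, 1005 without S3 and S4, 441 without S16 and S17 and 596 without S18 and S19. Igfbp7 lay above the sum by 5.83 ± 0.27 and Jaml by 4.02 ± 0.34; Jaml was lower in each single knockout than in DKO cells, at 2.33 and 3.26 against 8.1 ± 2.52 (SD, n = 3) RPKM. Gzmg and Gzmd, higher in Ikzf3 KO cells and not in DKO cells, lay below the sum, with -10.35 ± 1.52 and -7.25 ± 1.19. Their changes in Ikzf1 KO cells, which were not called, also enter this sum. Gzmg stood at 699 ± 421 RPKM in Ikzf1 KO and 90.8 ± 81.8 in Cre only cells, and Gzmd at 1480 ± 590 and 444 ± 381 (SD, n = 4 each). Neither Ikzf1 nor Ikzf3 was called: Ikzf1 departed by 0.23 (0.05 to 0.35 with single libraries left out) and Ikzf3 by 0.06 (-0.01 without S3 or without S5). Of 12 T cell markers 6 lay above the sum, among them Trac at 3.52 ± 0.51, and 6 did not pass. With the p adjusted over the list alone 10 lay above (camera adjusted p = 4.41e-07; adjusted p = 0.0717 with an estimated correlation). Of 19 immature NK genes 9 lay above and 1 below, with Cxcr3 at 2.99 ± 0.36; adjusted over the list alone 11 lay above and 2 below (camera adjusted p = 9.25e-05; adjusted p = 0.25 with an estimated correlation). Of 17 mature NK genes 4 lay below, with Klrg1 at -2.19 ± 0.38, none above and 13 did not pass. When adjusted over the list alone 1 lay above and 8 below (camera adjusted p = 0.00189; adjusted p = 0.174 with an estimated correlation).

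Genes changed in the same direction in the knockouts were counted for each pair. Ikzf1 KO and Ikzf3 KO cells shared 75 rises and 99 falls, with 33 genes changed in opposite directions, against 22.4 and 22 if the calls were independent. Ikzf1 KO and DKO cells shared 229 rises and 189 falls (28.6 and 29.6 if independent), with 8 opposite. Ikzf3 KO and DKO cells shared 167 rises and 254 falls (51 and 83.8 if independent), with 64 opposite. In all 3 knockouts 58 genes rose and 77, among them Jaml, fell. These counts share the same 4 control libraries, which alone makes fold changes correlate. With the controls split so that each side had its own 2, the shared counts had medians of 40, 163 and 108.5 over 6 arrangements. They ranged from 30 to 72, from 127 to 230 and from 92 to 180 with the choice of control libraries. Over all genes the fold changes correlated at 0.25, 0.60 and 0.28, with covariances of 0.0625, 0.187 and 0.113. In 100 simulations of unchanged groups the mean covariances were 0.0338, 0.0355 and 0.0308. The simulated correlations had medians of 0.55 (-0.49 to 0.92), 0.46 (-0.37 to 0.92) and 0.38 (-0.76 to 0.86), so the observed correlations lay inside the range without any effect. These ranges are so wide that few values could lie outside them. With the controls split, so that no control library was shared, the correlations ran from 0.05 to 0.29, from 0.37 to 0.58 and from 0.14 to 0.35. The mean covariances over the 6 arrangements were then 0.04, 0.164 and 0.0907. The median simulation called 0 genes, so its shared count of 0 says nothing about these overlaps.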

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

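All tests of explanations in this part except that of library scaling were chosen after the result was seen.

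Among 321 groups of 4 libraries tested, 19 values lay far from the other libraries of their group. Chance flags about 1 in 20 groups, and the share here was 5.92%. In Cre only libraries Gzmm stood at 0.858 RPKM in S18 against 1.74 to 1.83, and Igfbp7 stood at 0.172 in S16 against 0 in the others. Jaml stood at 15 in S17 against 20.1 to 21.1. In S19 Lag3 stood at 67 against 106, Mt2 at 20.3 against 56.6 to 61.6 and Pgk1 at 425 against 600 to 609. In the Ikzf1 KO library S13 Dll1 stood at 4.68 against 6.37 to 6.71, Tmem119 at 0.321 against 0.0868 to 0.0979 and Bst2 at 112 against 81.6 to 84.4. In S15 Dusp2 stood at 68.7 against 25.8 to 30.7, Eno1 at 463 against 392 to 400, Gzmk at 5.06 against 2.98 to 3.18 and Tgfbr2 at 40.3 against 27.4 to 27.7. In the Ikzf3 KO library S3 Cd300lb stood at 0.381 against 0.231 to 0.254, Ctsg at 78.8 against 37.9 to 42.9, Dmwd at 33.6 against 15.2 to 17 and Bst2 at 38.1 against 46.1 to 47.4. In S4 Gzmf stood at 14.6 against 93.4 to 102 and Tox at 2.2 against 1.65 to 1.71.

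The effect of one deletion differed with the state of the other gene in 657 genes, tested as the departure from the sum of the single log2 changes. Igfbp7 departed by 5.83, Chad by 4.83, Cd74 by 4.61, Ccl17 by 4.23 and Jaml by 4.02. Gzmg departed by -10.35, Gzmf by -8.75, Gzmd by -7.25, Gzme by -5.60 and Ctsg by -5.60. The call of Gzme was lost without S5 (adjusted p = 0.0536), and that of Ccl17 with voom on recovered reads.

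Several T cell receptor and CD3 transcripts were higher in the DKO than in the Cre only libraries. Of 5 measured alpha chain variable segments 4 rose, but of 3 delta chain variable segments none rose and 1 fell. A lower share of NK cells with more of every other cell type cannot be decided by these values. The 24 measured markers of 8 other cell types had a median log2 change of -0.07, with 6 of them higher and 5 lower. That median is 1.72 below the median of the T cell markers (SE 0.591, taken over genes). With only the first 5 of these types, as computed at first, the difference was 2.05. The measured markers include Itgax and Mmp9, at 91.3 and 62.3 RPKM in Cre only cells. Both fell in DKO cells, so the median of the markers does not measure other cells alone. T cells among the DKO cells remain open. Of the 20 T cell markers listed only 12 were measured, and Cd4, Cd5, Cd6, Cd8a and Cd8b1 were not among the genes kept. Of the 12 measured 8 rose, and all 16 beta chain variable segments with them, while Bcl11b and Cd3g did not pass. Of these 8, Cd28 was also called higher in Ikzf3 KO cells, at 26.2 to 46.5 RPKM against 18.6 to 21.4 in DKO cells. T cells cannot be told apart from T cell transcripts in NK cells, because there are no values per cell. Cells with intact genes among the DKO cells remain open too, since Ikzf1 was higher in DKO than in Ikzf1 KO cells (log2 change 0.63). S5, with the highest Ikzf1 of the DKO libraries (38.4 RPKM), had the lowest Cd3e (24.8 against 42.4 and 44.8). It had the highest Ccr7, however (3.67 against 1.96 in S6 and 2.45 in S7). S5 also belongs to the set of S5, S15, S18 and S19, in which Cd3d was lower by -1.74 ± 0.21 (limma with Benjamini-Hochberg, adjusted p = 0.00251). The order of T cell transcripts among the DKO libraries therefore cannot weigh this explanation. Expression of these genes in NK cells without both factors is a hypothesis that these data cannot decide.

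Ikzf3 KO libraries S3 and S4 stood apart from S1 and S2. A wrong genotype is argued against, because Ikzf3 was at most 16.4 RPKM in S3 and S4, below the lowest value of 37.7 in Cre only and Ikzf1 KO libraries, and Ikzf1 was at least 72.9, above the highest value of 38.4 in libraries without Ikzf1. A lower depth is argued against, because S3 and S4 had at least 12.6 megareads and S1 and S2 at most 11.1 megareads. A shared day of culture or preparation remains open: S3 and S4 correlated at 0.974, but no label gives a day, so it cannot be told apart from a difference between the animals. No biological explanation was tested.

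Of 38 cell cycle genes 9 were called higher in Ikzf1 KO cells and 29 did not pass, with a median log2 change of 0.79 over the list. The camera call of the list was lost with an estimated correlation (adjusted p = 0.647), and fry did not call it (adjusted p = 0.0622). The scaling of the libraries as the cause of this median is argued against only relative to the other genes. The list median was 0.83 after quantile normalization, and the median of all genes was -0.01 before it. Quantile normalization sets all libraries to the same distribution, so a shift of all genes would not be seen. Low cell cycle transcripts in the Cre only libraries S16 and S17 remain open: the median fell to 0.42 without them and rose to 1.13 without S18 and S19, so the direction held and the size did not. The set of S5, S15, S18 and S19 holds more of the Cre only than of the Ikzf1 KO libraries, and the rise was smaller against its controls S18 and S19. Unequal shares would therefore shrink the median rather than raise it, if the set shifts both genotypes alike. The median of 0.84 with the set as a term could be foreseen from this and is no separate test. The set was also picked from these same values. The part of the change that rests on S16 and S17 cannot be told apart from an effect of the deletion, because the Cre only group has only 4 libraries.

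Other splits of the same libraries were counted beside each result. For Ikzf1 KO against Cre only, 1 of 35 splits, the real one, called as many as its 634 genes, and the highest other split called 0. For Ikzf3 KO against Cre only it was also 1 of 35, with 1423 genes and at most 395 in another split. For DKO against Cre only it was 1 of 35, with 1872 genes and at most 643, and for DKO against Ikzf1 KO it was 1 of 35, with 750 genes and at most 7. By these counts chance can be excluded for these 4 only if the libraries of both groups are exchangeable. The pairs within the Ikzf3 KO and Cre only groups stand apart, and the highest other split put S1 and S2 with S16 and S17 for Ikzf3 KO and S16, S17 and S18 together for DKO against Cre only. With pairs as units, Ikzf3 KO against Cre only has just 3 splits, too few for a share under 5%. The set of S5, S15, S18 and S19, which runs across 3 genotypes, is also left out of these splits. With it as a term and without Ikzf3 KO libraries, 1982 genes were called in Ikzf1 KO and 3894 in DKO against Cre only and 2671 in DKO against Ikzf1 KO. The set was the highest of 72 groupings of these same values, and the spread of the Ikzf3 KO libraries was removed at the same time. Leaving out S3 and S4 alone gave 1698, 3642 and 2125. The larger counts are therefore no support for these results. For DKO against Ikzf3 KO, 4 of 35 splits called as many as the real 2012, with 2847 as the highest other, so chance cannot be excluded by this count. The 3 other splits kept S3 and S4 together, with S5, S1 or S2, which points to the structure of the Ikzf3 KO libraries. For the departure from additivity, 4 of 100 orders of the residuals called as many as the real 657, just under 5%. By this count chance can be excluded only if the residuals of all libraries are exchangeable. S3 and S4 and the Cre only pairs stand apart, and the highest other order called 1918 genes, which points to a structure of the samples.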

How the results depend on the processing

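Voom, the fits without pairs of libraries and those for the set of S5, S15, S18 and S19 were chosen after the results were seen; the other alternatives were planned. Pseudocounts, no filter, both rescalings, non-robust moderation and voom left all 6 counts within 1.5 times. The median of all genes lay within 0.02 of 0 without rescaling and with both rescalings. Of 3754 values of named genes under alternatives fixed in advance that kept all libraries in the fit, 3712 kept direction and call and 39 lost the call. With only the 2 groups in the fit 338 of 399 did and 61 lost it; with single libraries left out 3419 of 3975 did and 554 lost it. Of 472 gene results called, 279 were called under every alternative. No paired analysis was possible because the columns carry no replicate numbers; the replicate block, the fit of all 21 samples and the 3 comparisons with directly sorted cells were not run. Depth limits only weakly expressed genes.

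The filter of RPKM 5 left 7059 genes to test and gave 400 genes in Ikzf1 KO against Cre only, 421 in DKO against Ikzf1 KO, 1186 in DKO against Ikzf3 KO and 358 departing from additivity, as fewer genes were tested. Array weights, which gave S3 and S4 weights of 0.103 and 0.0854 and S14 one of 6.87, gave 3634 genes for Ikzf1 KO, 2367 for Ikzf3 KO and 4477 for DKO against Cre only, 3965 in DKO against Ikzf1 KO and 2406 departing from additivity. With only the 2 groups in the fit the counts were 1927 for Ikzf1 KO and 431 for Ikzf3 KO against Cre only, 1700 in DKO against Ikzf1 KO and 664 in DKO against Ikzf3 KO. Without S3 and S4 they were 1698 for Ikzf1 KO and 3642 for DKO against Cre only, 2125 in DKO against Ikzf1 KO and 1005 departing from additivity. Without S16 and S17 they were 366 for Ikzf1 KO, 555 for Ikzf3 KO and 1083 for DKO against Cre only, and without S18 and S19 740 for Ikzf3 KO. Without Ikzf3 KO libraries, the set as a term gave 1982 for Ikzf1 KO and 3894 for DKO against Cre only and 2671 in DKO against Ikzf1 KO, and only libraries outside the set gave 2993, 4655 and 3943; of named genes 226 of 226 and 212 of 213 values kept direction and call. Of 25 list tests called in these comparisons, 21 and 15 stayed. The set was picked from the same values, so what was kept with it is no independent support. Several of these fits had fewer samples and yet called more genes. The spread that the main fit shares was unequal between groups, with a median SD per gene of 0.363 in Ikzf3 KO and 0.123 in Ikzf1 KO libraries. Counts of comparisons without Ikzf3 KO rose where S3 and S4 or that whole group were left out or weighted down. No cause was tested apart from these fits.

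With single libraries left out the count ran from 332 to 728 in Ikzf1 KO, from 819 to 2985 in Ikzf3 KO and from 976 to 1856 in DKO against Cre only. It ran from 335 to 753 in DKO against Ikzf1 KO, from 1169 to 3080 in DKO against Ikzf3 KO and from 344 to 839 for the departure from additivity. With an estimated correlation 1 of the 53 list tests past the threshold stayed there; the self-contained test fry called 54, of which 35 were shared. With the controls split, the shared changes had medians of 40 for Ikzf1 KO with Ikzf3 KO, 163 for Ikzf1 KO with DKO and 108.5 for Ikzf3 KO with DKO, each side having fewer samples.

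The direction reversed as follows. The departure of Ikzf3 from additivity, 0.06 and not called, became -0.07 with array weights, -0.10 without S3 and S4 and -0.05 without S16 and S17, and ran from -0.01 to 0.12 with single libraries left out. Its adjusted p ran from 0.656 to 0.986 over all alternatives. Ribosome biogenesis and MYC targets turned without S3 and S4: higher in Ikzf3 KO against Cre only (adjusted p = 0.0176, in a range of 0.00652 to 0.758), lower and not called in DKO against Ikzf3 KO (adjusted p = 0.1, in a range of 0.00538 to 0.775) and in the departure from additivity (adjusted p = 0.191, in a range of 0.00581 to 0.662). The cause was not tested.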

Other observations

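Members of some further gene lists changed in DKO cells. Of 18 immediate-early and heat-shock genes outside AP-1, 6 fell in DKO against Cre only cells and 12 did not pass, with 7 falls adjusted over the list alone (camera adjusted p = 0.0285; adjusted p = 0.553 with an estimated correlation, 0.349 without S16 and S17, 0.0515 with voom and 0.0503 with fry). Of 14 genes of TGF-beta signalling 3 fell, with the receptor gene Tgfbr2 at -1.32 ± 0.22 (limma with Benjamini-Hochberg, adjusted p = 0.000691), and 1 rose, Tgfbr3 at 2.18 ± 0.15, while 10 did not pass; the counts adjusted over the list alone were the same (camera adjusted p = 0.202). Among 31 NK lineage transcription factors 4 rose and 7 fell, with Tcf7 at 1.82 ± 0.39, Klf2 at 1.72 ± 0.28, Stat4 at -1.19 ± 0.16 and Zeb2 at -0.85 ± 0.16, and 20 did not pass. Adjusted over the list alone 6 rose and 7 fell (camera adjusted p = 0.285). Of 8 genes of MHC class II presentation, 3 rose and 2 fell in DKO against Ikzf3 KO cells, with H2-Aa at 3.21 ± 0.54, and 3 did not pass. Adjusted over the list alone 3 rose and 3 fell (camera adjusted p = 0.517).

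Further lists were called by camera at an adjusted p below 0.05, and each of these calls was lost with an estimated correlation. In Ikzf1 KO against Cre only cells glycolysis was lower with none of 18 genes called (median -0.58, adjusted p = 0.00053). TGF-beta signalling was lower with 2 falls (0.017), cytokines and chemokines with 2 falls and 1 rise (0.0186) and checkpoint genes with 2 falls (0.0123). Fry called none of these, and all but TGF-beta signalling were lost without S16 and S17 (0.39, 0.429 and 0.224), and TGF-beta signalling without S18 and S19 (0.104). In Ikzf3 KO against Cre only cells markers of tissue residency and group 1 innate lymphoid cells (6 falls, 2 rises, 0.0448) and interferon-stimulated genes (3 falls, 0.021) were lower. Both were lost without S16 and S17 (0.518 and 0.0906), the former also with voom (0.0621) and the latter without S3 and S4 (0.155) and with fry (0.108). In DKO against Cre only cells the cell cycle list was higher (4 rises, 2.63e-05), lost without S16 and S17 (0.157) and with fry (0.111). Markers of group 3 innate lymphoid cells were higher (1 rise, 0.0457), lost without S3 and S4 (0.105), without S18 and S19 (0.232), with voom (0.0644), with the set of S5, S15, S18 and S19 as a term (0.187) and with only libraries outside it (0.276).

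In DKO against Ikzf1 KO cells mature NK markers (6 falls, 1 rise, 0.00946), glycolysis (2 falls, 0.000983) and checkpoint genes (2 falls, 0.00946) were lower and gamma delta T cell markers higher (4 rises, 1 fall, 0.0105). With only libraries outside the set these were lost (0.104, 0.427, 0.0557 and 0.0557), and glycolysis with fry as well (0.131). In DKO against Ikzf3 KO cells immature NK markers were higher (9 rises, 3 falls, 0.00333) and mature NK markers lower (7 falls, 1 rise, 0.00333). Cell cycle genes (6 rises, 0.00814), gamma delta T cell markers (5 rises, 1 fall, 0.0167) and markers of group 3 innate lymphoid cells (3 rises, 0.0174) were higher and checkpoint genes lower (7 falls, 3 rises, 0.0174). The last 4 were lost without S3 and S4 (0.527, 0.0666, 0.0514 and 0.0726), cell cycle genes with fry (0.276) and checkpoint genes with voom (0.0554). Above the sum of the single deletions lay homing and adhesion (6 genes above, 0.00189), cytokines and chemokines (3 above, 0.00189), gamma delta T cell markers (4 above, 1 below, 0.00895) and TGF-beta signalling (3 above, 0.0231). Below it lay cytotoxic effectors (5 below, 3 above, 0.0188), glycolysis (none called, 0.00895), cell cycle genes (1 below, 0.0212) and markers of mast cells and group 2 innate lymphoid cells (3 below, 0.0312). Without S3 and S4 the cytokine, gamma delta T cell, cytotoxic, glycolysis and mast cell lists were lost (0.0686, 0.0605, 0.0686, 0.0556 and 0.0686), without S16 and S17 the cell cycle list (0.548) and without S18 and S19 glycolysis, TGF-beta signalling and the mast cell list (0.316, 0.0973 and 0.0509). Fry did not call the cytokine, TGF-beta, glycolysis and cell cycle lists (0.0518, 0.0518, 0.318 and 0.46).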
